A study of Homo sapiens with 6 samples.

How the data were processed

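RNA sequencing was done on 6 libraries of SK-OV-3, an established human ovarian cancer cell line. Of these, 3 came from cells kept in plain medium (control 1, 2 and 3) and 3 from cells given fulvic acid (FA 1, 2 and 3), a water-soluble fraction of humic substances, at 100 µg/ml for 48 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and double-stranded cDNA was ligated to adaptors, size-selected and amplified by PCR. The protocol does not say whether strand was kept. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

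The deposited file is 1 table of 459 genes. Per the file headers it holds raw read counts per gene and library, FPKM values (fragment counts scaled by gene length and library size) per gene and library, and a false discovery rate (FDR) and a log2 fold change for the comparison of FA with control. The counts and FPKM values, the FDR (an adjusted p-value) and the log2 fold change were all made by the authors. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool and the test are not given in the sources used here. In the authors' deposited table every gene had an absolute log2 fold change of at least 1.00 and an FDR of at most 0.00977, so the table holds genes past limits of about 1 and 0.01. Genes outside these limits were not analysed here, and the absence of a gene from the table says nothing of its expression.

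Of the 459 genes, 399 carried an Ensembl gene identifier. All 399 were found in GENCODE release 29 (Ensembl 94, GRCh38), each with the same symbol as in the table, and all were protein-coding. The other 60 were numbered gene models without identifier or position. Coordinates are those of GENCODE release 29. In 37 of the 399 genes, over 20% of the exonic bases were also exonic in another gene, and counts of these may be shared.

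The depth of each library was recovered from counts and FPKM together. The ratio of both values, over 180 genes with at least 200 counts in every library, gave the relative depth. Its absolute scale came from 16 genes with a single annotated transcript and at least 100 counts in each library. The implied totals were 43500000, 48800000 and 47400000 fragments for control 1, 2 and 3, and 39900000, 44700000 and 50900000 for FA 1, 2 and 3. The listed genes held 561604 to 796663 counts per library, between 1.34% and 1.68% of these totals. The library factors behind the authors' log2 fold changes were also recovered by least squares over the same 180 genes. With them 90% of the authors' log2 fold changes of these 180 genes, on which the factors were fitted, were met within 0.00064. The log2 fold changes of the authors' deposited table lay 0.059 ± 0.0023 (SD over 180 genes) above those scaled by depth.

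The direction, log2 fold change and FDR of the authors were taken as the main result, since genes outside the table are needed to repeat the test. As a measure of spread, the counts of the 459 genes were refitted with edgeR 4.0.16 (R 4.3.3; quasi-likelihood test, control and FA as the only term, library sizes set to the recovered depth, Benjamini-Hochberg adjustment over the 459 genes, threshold 0.05). Standard errors of log2 fold changes were derived from that fit, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. These genes were selected on the same libraries, so the refit is not independent evidence. Levels are given as FPKM, mean ± SD with n = 3 per group. The refit was tested on simulated counts for the 459 genes with 200 genes changed. It recovered 70.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 3-fold, and called 1.93% of 259 unchanged genes. The simulation took its spread from these selected genes, drew each gene independently and balanced changes up and down. Its rates may therefore be better than those in the real libraries.

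The 36 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added. For lists with at least 5 members in the table (8 lists), higher and lower calls were compared with those of the other listed genes by a two-sided Fisher's exact test (scipy 1.17.1) with Benjamini-Hochberg adjustment over the 8 lists. Whether a list is over-represented was not tested, since the genes that could have been called are not known. The named genes are CYP1A1, the 12 genes with the largest authors' log2 fold change in each direction among annotated genes with an FDR under 0.05, a mean of at least 50 counts and no overlap between groups, up to 4 members of each list by FDR, and CYP1B1, AHRR, TIPARP and NQO1. NQO1 was not analysed here. This gave 80 genes, and 100 were chosen in all, the others after their values were seen. Of the genes given by the rule, 2 are not reported here by name and are part of the counts only.

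Alternatives were stricter limits on the authors' values, a minimum mean of 50 counts, the replicate number as a block, TMM and DESeq2 size factors computed over the listed genes, column totals, the DESeq2 1.42.0 Wald test, limma 3.58.1 on log2 CPM (0.5 added to each count) and on log2(FPKM + 1, 0.1 or 0.01), and each library left out in turn. The authors' own library factors, the removal of a trend on GC content within each group, and the test of one list without CYP1A1 were added after seeing the data. Pairs of libraries of one group were checked for duplicates by chi-square. The pair least apart, FA 1 and FA 2, had a chi-square of 7.09 per degree of freedom, so all 6 libraries were kept as separate samples. The replicate numbers were not used as pairs.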

Results

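The transcriptome of SK-OV-3 ovarian cancer cells was compared between 3 libraries from cells exposed to fulvic acid (FA) at 100 µg/ml for 48 h and 3 libraries from untreated cells. The comparison asks which genes FA changes in these cells. The title of the study names CYP1A1 among them. Implied depth was 39900000 to 50900000 fragments per library, with overlapping ranges in both groups, and the listed genes held 561604 to 796663 counts per library. Of the 459 listed genes, 41 had a mean below 50 counts over the 6 libraries.

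FA was accompanied by higher levels of 117 genes and lower levels of 342 genes in the authors' deposited table, so that 74.5% of the listed genes were lower. CYP1A1, a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons, had the largest change in either direction. Among the lower genes with a mean of at least 50 counts and a gene identifier, the largest decreases were in KRT81 (a hair keratin), CDH6 (a cadherin), MMP7 (matrilysin, a matrix metalloproteinase) and EDN1 (the precursor of endothelin-1). In all 459 genes the 3 FA libraries lay entirely on one side of the 3 control libraries, a separation that 10% of unselected genes would show by chance. In the edgeR refit, which is not independent of the selection, all 459 genes passed an adjusted p of 0.05, with a median standard error of 0.21 on the log2 scale. Scaling by column totals or by the authors' library factors kept 117 higher and 342 lower with 0 changes of sign. These scalings moved the median log2 fold change by only 0.24 and 0.058. Every listed gene had an absolute authors' log2 fold change of at least 1.00, so the signs were fixed in advance. TMM computed over the listed genes alone by construction centres the typical listed gene, adding 1.24 to the median log2 fold change. With it edgeR called 117 genes higher and 81 lower (40.9% lower), and 99 of the 459 genes changed sign under TMM or DESeq2 size factors of this kind. With both, CDH2, MMP2, COL1A1, COL17A1, CXCL1, IFITM3, OAS3, UHRF1, WNT10A, BMF, CA9 and CYP2J2 stayed lower but did not pass the edgeR threshold. Which genes lost their call or changed sign follows largely from the size of their decrease, here and wherever it is stated below.

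**Figure D1:**
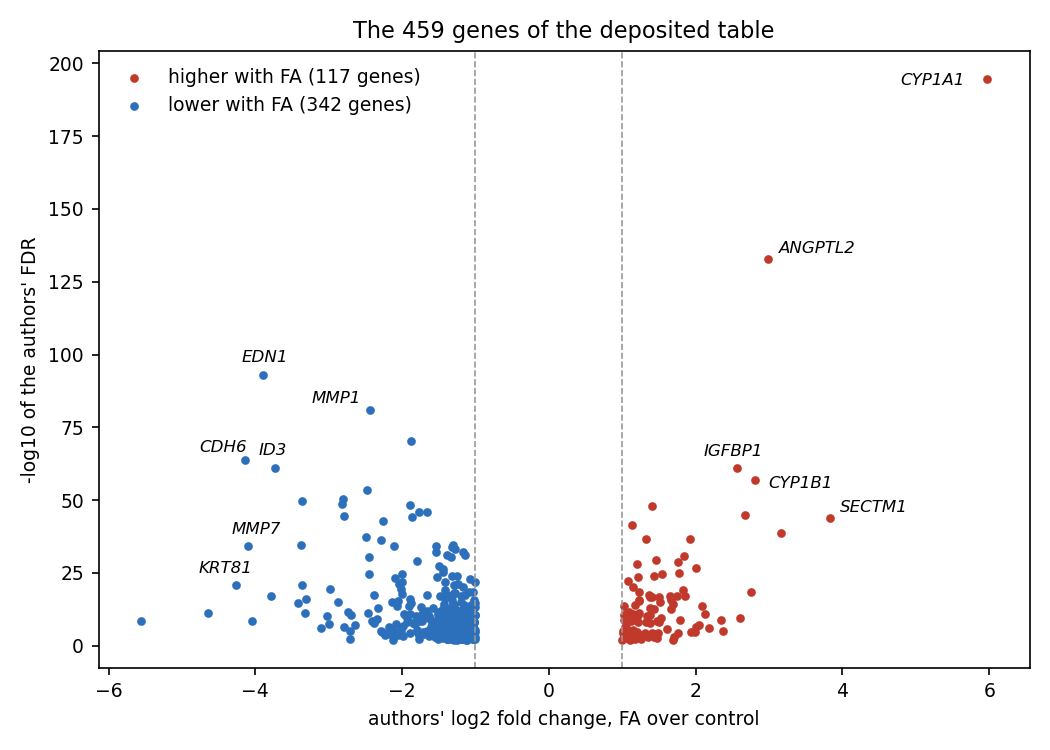
Log2 fold change in the authors' deposited table of FA over control (x axis) against the -log10 of its FDR (y axis) for the 459 listed genes, with 117 higher in red and 342 lower in blue; dashed lines mark a log2 fold change of 1 in either direction. CYP1A1 stands at 5.98 in the authors' deposited table, at the upper right.

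CYP1A1 (ENSG00000140465, chromosome 15, positions 74719542 to 74725610, minus strand) rose from 0.242 ± 0.044 FPKM in the control libraries to 15.8 ± 0.58 FPKM with FA. Its counts were 23, 35 and 35 in the control libraries and 1597, 1851 and 1985 in the FA libraries. The fold change was 60.2 (log2 5.91, SE 0.19; edgeR adjusted p = 3.8e-10). The authors' deposited table gives a log2 fold change of 5.98 with an FDR of 1.9e-195. No other gene's exons overlap those of CYP1A1 in the annotation used.

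CYP1A1 belongs to a fixed list of 20 targets of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. Of this list, 6 genes were in the table, and 5 of these were higher. CYP1B1, a related cytochrome P450 (chromosome 2, positions 38066973 to 38109902), rose 6.75-fold, from 40.1 ± 8.5 to 270.4 ± 18.8 FPKM, the highest FA level among the 6 members in the table. Of the exonic bases of CYP1B1, 13.0% are shared with its antisense gene, and the use of strand in counting is not given. TIPARP, an ADP-ribosyltransferase that limits AHR activity, rose 3.44-fold, from 6.06 ± 1.0 to 20.9 ± 0.52 FPKM. AHRR, the AHR repressor, rose 3.28-fold, from 0.892 ± 0.17 to 2.99 ± 0.68 FPKM. Among members named after their values were seen, ALDH3A1, an aldehyde dehydrogenase, rose from 30.3 ± 5.2 to 67.1 ± 4.3 FPKM, and NEDD9, a scaffold protein of focal adhesions, was the member that fell, from 0.392 ± 0.080 to 0.0888 ± 0.046 FPKM. The edgeR adjusted p was at most 3.8e-05 for these 6 genes. Higher calls were more frequent in this list than among the other listed genes, of which 112 of 453 were higher (Fisher's exact test, two-sided, p = 0.0048, adjusted p = 0.038 over 8 lists). Since CYP1A1 is the gene of the study's title, the list is not independent of the study's finding, and without CYP1A1 the adjusted p was 0.13.

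**Figure D2:**
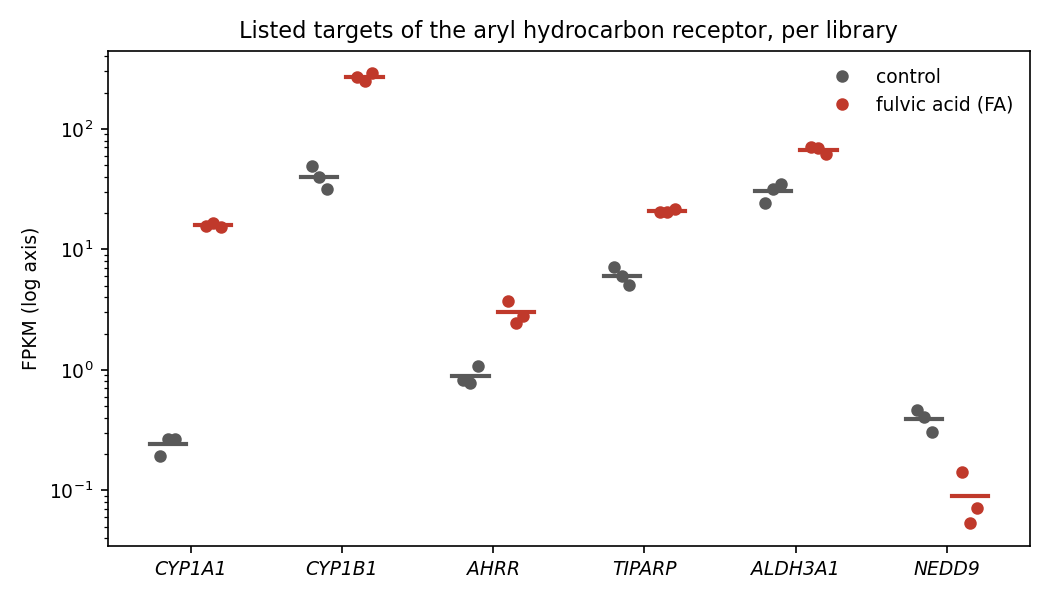
FPKM on a log axis (y) for the 6 listed AHR targets (x); each point is a library, grey for control and red for FA, and the bar is the mean of 3 libraries. CYP1A1, CYP1B1, AHRR, TIPARP and ALDH3A1 lie higher in all FA libraries and NEDD9 lower, with CYP1A1 moving from 0.242 to 15.8 FPKM.

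Of the 12 annotated genes with a mean of at least 50 counts that rose most, CYP1A1 and CYP1B1 were on that list and the others were not. SECTM1, a secreted and transmembrane protein (chromosome 17, positions 82321024 to 82334074), rose 13.6-fold, from 0.812 ± 0.33 to 11.2 ± 0.27 FPKM. ANGPTL2, a secreted angiopoietin-like protein (chromosome 9, positions 127087332 to 127122883), rose 7.62-fold, from 3.55 ± 0.39 to 27.1 ± 1.1 FPKM. IGFBP1, which binds insulin-like growth factors, rose 5.65-fold to 50.3 ± 2.7 FPKM, and IL1RN, the interleukin-1 receptor antagonist, rose 5.81-fold to 1.15 ± 0.12 FPKM. The serine protease gene PRSS33 rose 6.44-fold, the endothelial nitric oxide synthase gene NOS3 4.19-fold, the glycosyltransferase gene B4GALNT2 3.85-fold and the ferlin gene FER1L6 3.94-fold. SH3BGR rose 8.56-fold, from 0.733 ± 0.072 to 5.56 ± 0.066 FPKM, but 62.8% of its exonic bases are shared with the read-through gene WRB-SH3BGR, named after its values were seen, which fell, so its counts are uncertain. The edgeR adjusted p was at most 2.1e-05 for each of these genes.

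In the list of antigen presentation genes, HLA-DMB, which with HLA-DMA loads peptides onto class II molecules, rose 6.11-fold from 3.06 ± 0.80 to 19.0 ± 0.81 FPKM. HLA-DMA (1.59 ± 0.66 to 3.28 ± 0.59 FPKM) and CD74, the class II invariant chain (1.43 ± 0.22 to 2.85 ± 0.13 FPKM), also rose. These were the 3 members of that list of 19 in the table. All 4 listed members of cholesterol synthesis and uptake rose: INSIG1, a regulator of the pathway, 2.63-fold, and the enzymes MSMO1, IDI1 and HMGCS1 2.24-fold, 2.17-fold and 1.99-fold. ATF3 and DNAJB9, of the stress response list, rose 2.41-fold and 2.12-fold. These lists had fewer than 5 members in the table and were not tested as groups.

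The list of TGF-beta and YAP targets had the most members in the table, 13 of 23, and all 13 were lower. ID3 and ID1, inhibitors of helix-loop-helix transcription factors, fell from 17.8 ± 3.5 to 1.28 ± 0.11 FPKM and from 351.4 ± 52.4 to 48.8 ± 9.6 FPKM. TGFBI, a secreted matrix protein, fell from 11.4 ± 1.6 to 1.06 ± 0.33 FPKM, and PMEPA1 from 17.5 ± 0.65 to 4.97 ± 0.55 FPKM. The edgeR adjusted p was at most 3.1e-07 for these 4 genes. Set against the other listed genes, the 13 of 13 did not pass after adjustment (Fisher's exact test, two-sided, p = 0.046, adjusted p = 0.18). Because 74.5% of all listed genes were lower, this is the smallest p that a list of this size can reach with lower genes, and the same holds for the lists of 9, 8 and 7 genes that were all lower.

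All 9 listed members of the list of collagens and matrix were lower. COL8A1 fell from 0.656 ± 0.13 to 0.0716 ± 0.024 FPKM, COL7A1 from 6.06 ± 0.39 to 1.63 ± 0.22 FPKM, COL5A1 from 13.5 ± 0.91 to 3.55 ± 0.41 FPKM, and COL17A1 from 2.80 ± 0.14 to 1.10 ± 0.24 FPKM. The 4 members of the mesenchymal list in the table were also lower: the matrix glycoprotein gene SPARC fell from 40.7 ± 3.9 to 7.01 ± 1.2 FPKM, MMP2 from 8.09 ± 0.95 to 2.95 ± 0.24 FPKM, N-cadherin (CDH2) from 4.49 ± 0.54 to 1.73 ± 0.11 FPKM, and LOXL2, which changed sign under TMM over the listed genes, from 33.6 ± 5.3 to 14.2 ± 0.78 FPKM. Of 3 members of the epithelial list in the table, E-cadherin (CDH1) rose from 11.2 ± 0.25 to 22.6 ± 1.5 FPKM and 2 fell, among them ITGB6 from 5.12 ± 1.9 to 0.892 ± 0.36 FPKM. Fisher's exact test against the other listed genes gave p = 0.12 (adjusted p = 0.32), the smallest p possible with 9 lower genes, and so does not tell the list from the others.

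The other genes with the largest decreases were of mixed function. MMP7 (chromosome 11, positions 102520508 to 102530753) fell from 113.6 ± 8.2 to 6.39 ± 3.8 FPKM (17.8-fold lower), EDN1 (chromosome 6, positions 12290363 to 12297194) from 9.04 ± 0.34 to 0.578 ± 0.10 FPKM (15.5-fold lower), and CDH6 (chromosome 5, positions 31193750 to 31329146) from 1.96 ± 0.25 to 0.0972 ± 0.024 FPKM (18.3-fold lower). KRT81 fell from 1.70 ± 0.16 to 0.0840 ± 0.050 FPKM, and it has close keratin paralogs with which reads can be shared. PADI3, NKAIN4, SRGN and LYPD1 had log2 fold changes of -3.47, -3.41, -3.36 and -3.04. Of the exonic bases of LYPD1, 48.9% are shared with other genes, GPR39 most, so its counts may be shared. The edgeR adjusted p was at most 1.6e-06 for these 8 genes.

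Members of the inflammatory and interferon lists in the table were mostly lower. Of 7 listed members of the NF-kB and cytokine list, 6 were lower: MMP1 fell from 31.4 ± 2.9 to 5.55 ± 0.29 FPKM, SAA1 from 47.5 ± 6.0 to 10.6 ± 1.4 FPKM, SAA2 from 11.3 ± 0.79 to 1.88 ± 0.14 FPKM, and CXCL1 from 103.1 ± 9.0 to 39.3 ± 2.5 FPKM. SAA1 and SAA2 are near-identical, so the share of each is uncertain. LCN2, the siderophore-binding lipocalin, rose from 335.7 ± 45.9 to 653.4 ± 27.8 FPKM. Of 7 members of the list of interferon-stimulated genes in the table, IFITM3 (629.6 ± 125.1 to 227.3 ± 25.1 FPKM), IFITM1 (88.2 ± 14.9 to 26.8 ± 3.7 FPKM) and OAS3 (6.66 ± 0.36 to 2.47 ± 0.25 FPKM) were among 6 that fell, and ISG20 rose from 1.78 ± 0.23 to 5.92 ± 0.76 FPKM. Neither list passed the test of direction against the other listed genes (Fisher's exact test, adjusted p = 0.78 for both). All 8 members of the complement and coagulation list in the table were lower (Fisher's exact test, p = 0.21, adjusted p = 0.34, the smallest p possible with 8 lower genes). Among these, tissue factor (F3) fell from 91.8 ± 12.3 to 30.1 ± 0.37 FPKM, urokinase (PLAU) from 44.1 ± 5.8 to 14.6 ± 1.2 FPKM and SERPINA3 from 8.53 ± 2.4 to 2.08 ± 0.17 FPKM. PLAUR, named after its values were seen, fell 2.18-fold and changed sign under TMM over the listed genes. Over 20% of the exonic bases of PLAU, SERPINA3, IFITM1, IFITM3 and ITGB6 are shared with other genes.

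All 7 members of the DNA replication and G1/S list in the table were lower, while none of the 30 genes of the G2/M and mitosis list was among the 459. MCM5, a subunit of the replicative helicase, fell from 9.44 ± 1.5 to 2.71 ± 0.61 FPKM, UHRF1 from 6.59 ± 0.64 to 2.83 ± 0.24 FPKM, E2F1 from 9.02 ± 0.69 to 3.88 ± 0.36 FPKM and E2F2 from 2.23 ± 0.068 to 1.01 ± 0.11 FPKM. E2F1, E2F2 and CDT1, the last named after its values were seen, changed sign under TMM over the listed genes. Fisher's exact test against the other listed genes gave p = 0.20 (adjusted p = 0.34), the smallest p possible with 7 lower genes. Of 5 members of the immediate early list in the table, CYR61 (50.4 ± 3.2 to 16.6 ± 1.7 FPKM), JUNB (120.1 ± 20.9 to 50.9 ± 3.5 FPKM) and MYC (81.0 ± 7.4 to 38.6 ± 1.4 FPKM) were among 4 that fell, with ATF3 higher. JUNB, MYC and EGR3, the last named after its values were seen, changed sign under TMM over the listed genes, and the list did not pass the test of direction (Fisher's exact test, adjusted p = 1).

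Several lists had few members in the table. The metallothioneins MT2A and MT1X fell from 107.8 ± 19.2 to 18.5 ± 2.7 FPKM and from 8.22 ± 1.6 to 1.92 ± 0.71 FPKM. They belong to a family of close copies. The apoptosis regulators TNFSF10 (the death ligand TRAIL) and BMF fell from 15.7 ± 3.6 to 3.46 ± 0.40 FPKM and from 2.16 ± 0.14 to 0.782 ± 0.17 FPKM. The small heat shock proteins CRYAB and HSPB1 fell to 1.68 ± 0.39 and 75.8 ± 5.5 FPKM, DKK1, WNT10A and HES1 to 0.917 ± 0.13, 3.94 ± 0.40 and 5.51 ± 1.6 FPKM, and the cathepsin gene CTSB fell 2.22-fold. CYP2J2, CYP26B1 and SULT1A1 of the xenobiotic list and the hypoxia target CA9 fell 2.49-fold, 2.19-fold, 2.26-fold and 2.55-fold. CA9 had a mean below 50 counts, and 38.5% of its exonic bases are shared with other genes. For CRYAB this share is 20.6%, so counts of both may be shared. HSPB1, HES1, CTSB, CYP26B1 and SULT1A1 changed sign under TMM over the listed genes. None of the genes written in 14 of the fixed lists was among the 459. These were the lists of NRF2 targets, p53 targets, G2/M and mitosis, replication-dependent histones, fatty acid synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, ovarian cancer markers, stem cell and drug resistance markers, and markers of leukocytes, of endothelium and of liver or intestine. Each list holds only some genes of its class, so this does not say that no gene of the class was in the table. HIST1H3E, a replication-dependent histone H3 gene outside the list of 19 and named after its values were seen, rose from 0.742 ± 0.20 to 1.69 ± 0.45 FPKM (edgeR adjusted p = 0.00064), and it has near-identical copies with which reads can be shared. The libraries were made from captured polyadenylated RNA, so histone transcripts without a poly(A) tail would largely be missed. NOS3 was likewise outside the endothelial list. The fibroblast marker list had 1, COL1A1, which fell from 0.469 ± 0.080 to 0.214 ± 0.093 FPKM. In all, 89 distinct genes of the 36 lists were in the table. All 89 passed the authors' FDR and an edgeR threshold of 0.05 adjusted over the list alone. The table holds only genes past the authors' limits, and all 459 passed the refit, so this says nothing further about the lists.

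**Figure D3:**
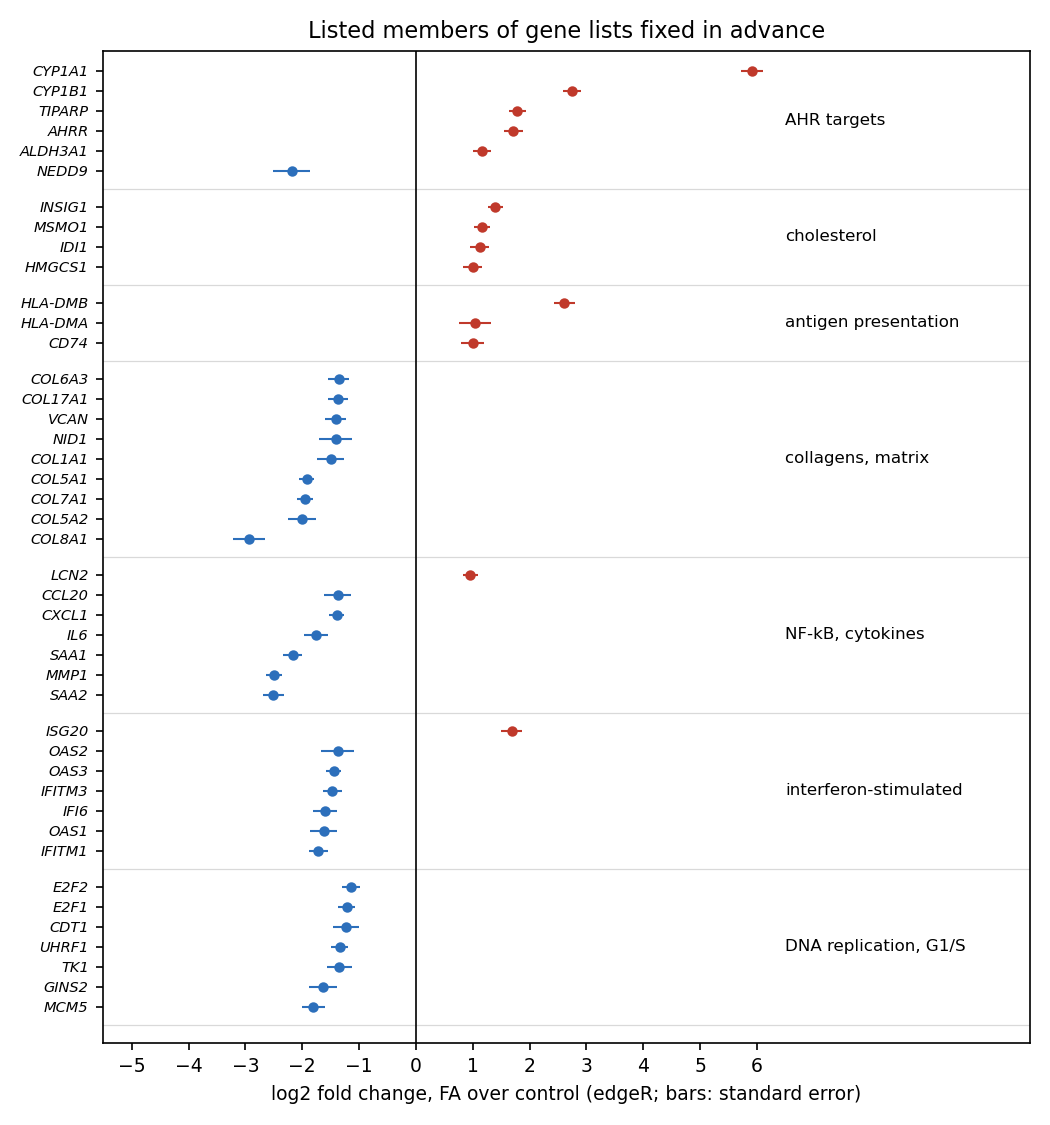
Log2 fold change of FA over control (x axis, edgeR refit scaled by recovered depth; bars are standard errors, n = 3 per group) for the listed members of 7 gene lists (y axis). All 9 genes of the matrix list and all 7 of the DNA replication and G1/S list lie below 0; CDT1, E2F1 and E2F2 change sign when TMM is computed over the listed genes.

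The control libraries deviated from their mean along GC content, control 1 most. Over 371 annotated genes with a mean of at least 50 counts, the deviation from the group mean had a Spearman correlation with GC content, across genes, which are not independent replicates, of -0.72 in control 1, 0.33 in control 2 and 0.64 in control 3, and of 0.081, 0.13 and -0.22 in FA 1, 2 and 3. Deviations within a group sum to 0 for each gene, so the values of one group are not independent of each other. Without control 1, and likewise without any other single library, 117 listed genes stayed higher and 342 lower in the edgeR refit. The groups did not overlap in any of the 459 genes, so leaving out a library could not reverse a direction. It therefore does not show whether the deviation of control 1 matters for the comparison.

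**Figure D4:**
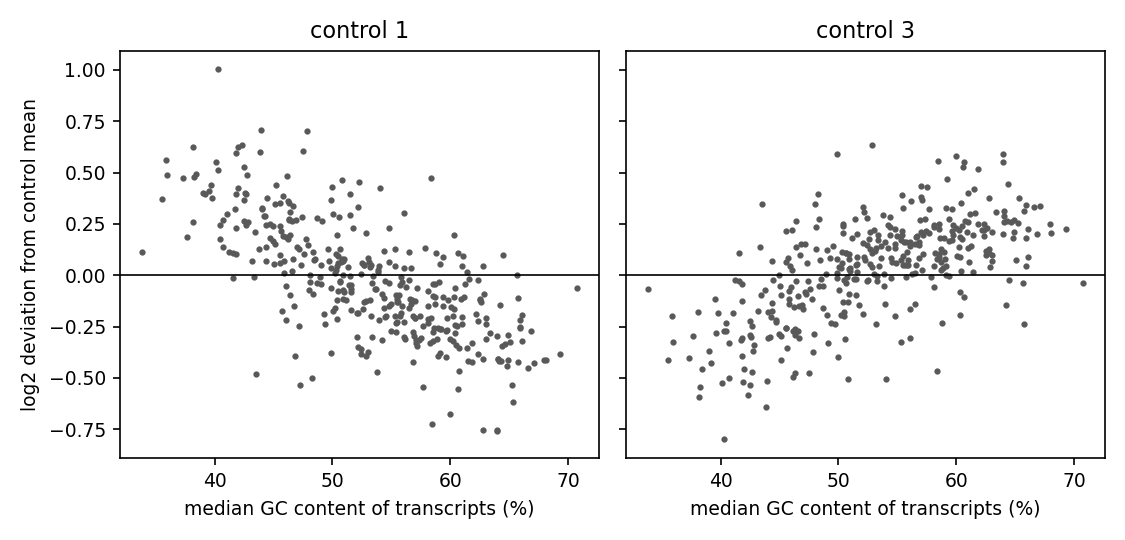
Log2 deviation of control 1 (left) and control 3 (right) from the mean of the 3 control libraries (y axis) against the median GC content of each gene's annotated transcripts (x axis, percent); each point is 1 of 371 genes. Control 1 slopes down (Spearman correlation -0.72) and control 3 up (0.64), which are not independent since deviations of the 3 libraries sum to 0.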

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

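Among the calls of the authors' deposited table, an absolute log2 fold change of at least 1.5 left 172 genes (39 higher, 133 lower), at least 2 left 84 (17 higher, 67 lower), and an FDR under 1e-05 left 307 (77 higher, 230 lower). In the refit, scaling computed from the listed genes alone lowered the calls from 459 to 198 with TMM (81 lower) and to 203 with DESeq2 size factors (86 lower), and the genes whose groups did not overlap from 459 to 232 with TMM. By construction such scaling sets the typical listed gene to no change: both moved the median log2 fold change by 1.24, so which genes lost their call or changed sign follows largely from the size of their decrease, and column totals moved it by 0.24. Of 99 named genes besides CYP1A1, 67 kept direction and call with either scaling, and the call, though not the direction, was lost for 16 with TMM and 18 with DESeq2 size factors, among them CDH2, CXCL1, IFITM2, MMP10 and IGFBP6. The log2 fold changes that changed sign, with values for TMM and then DESeq2 size factors, were those of CDH3 (0.053, 0.045), CDT1 (0.031, 0.023), CTSB (0.097, 0.089), CYP26B1 (0.12, 0.11), E2F1 (0.028, 0.020), E2F2 (0.10, 0.093), EGR3 (0.16, 0.15), HES1 (0.071, 0.065), HSPB1 (0.13, 0.12), KRT86 (0.046, 0.036), MYC (0.16, 0.15), PADI1 (0.020, 0.012), PLAUR (0.12, 0.11) and SULT1A1 (0.072, 0.065), and with TMM alone JUNB (0.00696) and LOXL2 (6.1e-05). Without CYP1A1, an alternative added after seeing the data, the AHR target list lost its call (Fisher's exact test, adjusted p = 0.13), which lay between 0.029 and 0.043 under its other alternatives. Of these, the replicate block and each library left out kept all 459 calls and directions, so they only repeated the main test. The scalings over the listed genes were not applied to this test, so the range does not show stability. CYP1A1 kept its direction and call under every alternative, with a log2 fold change of 5.78 to 7.16 in the count-based fits and 3.75 on the log2(FPKM + 1) scale, which understates low genes. The replicate numbers did not pair the libraries: same-numbered deviations had correlations of -0.086, 0.21 and -0.54 over 180 genes. Between libraries of unlike number the correlations ran from -0.46 (control 1 with FA 2) to 0.51 (control 1 with FA 3). Variation shared between the groups under other numbers therefore stays open. The fit with the replicate block also called 459 genes (CYP1A1 log2 fold change 5.92). Leaving out each library in turn, the DESeq2 Wald test, limma on log2 CPM and the authors' library factors kept every tested gene on its side of the threshold, and limma on log2(FPKM + 1, 0.1 or 0.01) called 458, but these genes were selected on the same libraries, so this stability was partly built in. The directions could not change when a library was left out, since the groups did not overlap in any of the 459 genes. Removing the within-group GC trend leaves the difference between groups almost fixed by construction and says nothing on stability. Depth limits the 41 genes below a mean of 50 counts, where the standard error reached 0.57 on the log2 scale.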

Other observations

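The gene families, and the tests of the patterns weighed in this part, were chosen after the values were seen. The listed matrix metalloproteinases MMP1, MMP2, MMP7 and MMP10 were all lower, with log2 fold changes between -4.16 and -1.45. So were the listed keratins KRT5, KRT6A, KRT81 and KRT86 (between -4.31 and -1.20) and the peptidylarginine deiminases PADI1, PADI2 and PADI3 (between -3.47 and -1.22), although KRT86 and PADI1 changed sign under TMM over the listed genes. KRT5, a basal epithelial keratin, fell from 29.1 ± 5.0 to 5.74 ± 0.67 FPKM. All 3 listed interferon-induced transmembrane genes fell, IFITM2 from 234.9 ± 48.9 to 89.4 ± 4.8 FPKM, and they share sequence with each other. With TMM and with DESeq2 size factors over the listed genes, MMP2, MMP10, IFITM2 and IFITM3 stayed lower but did not pass the edgeR threshold. Of all listed genes 74.5% were lower, so a small family with every member lower does not by itself stand out. MMP1, MMP7 and MMP10 lie close together on chromosome 11, as do these transmembrane genes. The keratins lie together on chromosome 12 and the deiminases on chromosome 1, so members need not be independent cases.

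Other families split. Among cadherins CDH1 was higher while CDH2, CDH3 and CDH6 were lower, CDH3 with a change of sign under TMM over the listed genes. Among genes of insulin-like growth factor binding, IGFBP3 rose from 237.7 ± 12.6 to 602.4 ± 14.3 FPKM along with IGFBP1, while IGFBP7 fell from 161.4 ± 36.0 to 38.9 ± 5.6 FPKM and IGFBP6 from 63.4 ± 14.9 to 22.1 ± 2.6 FPKM. With both scalings over the listed genes, CDH2 and IGFBP6 stayed lower but did not pass the edgeR threshold. The interleukin-1 receptor genes IL1R1 and IL1R2, which encode the signalling and the decoy receptor, rose 2.49-fold and 3.64-fold together with the antagonist gene IL1RN. Of the 60 unannotated gene models, 25 were higher (41.7%), against 92 of 399 annotated genes (23.1%; Fisher's exact test, two-sided, p = 0.0038), and their median level was 107.2 counts against 307.2. This p is unadjusted and counts each model as independent. The positions of the models are not known, so some may be pieces of the same transcript.

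The excess of lower over higher genes was set against library scaling and GC content. Beyond an absolute log2 fold change of 1.5 the authors' deposited table held 133 lower and 39 higher genes, and all authors' values would have to be shifted up by 0.331 to make the numbers equal, at 84 each. The values of the authors' deposited table lay 0.059 ± 0.0023 above those scaled by depth. A change to depth would thus shift them down and widen the excess, so the choice between these scalings does not account for it. Lower genes had a median GC content 3.91 percentage points above that of higher genes (54.0% against 50.1%, 95% bootstrap interval 0.77 to 6.74), while the log2 fold change of the authors' deposited table had a Spearman correlation of -0.010 with GC content across 371 genes, so a part played by GC content stays open, since genes outside the table would be needed to fit a trend between the groups. A change in total RNA per cell, and an effect of FA itself, also stay open and untested.

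Control 1 stood apart from the other control libraries, with a chi-square per degree of freedom of 37.6 to control 2 and 77.2 to control 3, against 16.6 between those. A GC content bias between libraries is a candidate explanation that stays open, since the Spearman correlation of -0.72 between the deviations of control 1 and GC content across genes is itself what prompted it and is no separate test. With GC content held fixed, the partial Spearman correlation of transcript length with the deviations of control 1 was 0.15. The length used was the median over all annotated transcripts of a gene, which need not be the length expressed. A part played by transcript length therefore stays open. Whether such a bias affects the comparison of FA with control stays open, since a trend removed within each group leaves the difference between groups almost fixed by construction. Any other difference between these libraries that follows GC content was not tested.

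SH3BGR rose while WRB-SH3BGR, a read-through model that shares its exons on chromosome 21, fell from 1.74 ± 0.33 to 0.347 ± 0.30 FPKM, a call lost with both scalings over the listed genes. A candidate explanation is that counts passed from one model to the other. Their summed counts rose, from 3.20 ± 0.43 CPM to 6.88 ± 0.61 CPM of recovered depth (log2 ratio 1.11, SE 0.13), which argues against such a transfer as the whole cause. Counts taken from the third model of this locus, WRB, which was not analysed here, stay open, as does higher transcription of SH3BGR with FA.

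Of the 10 ways to split the 6 libraries into groups of 3, the real split gave 459 genes in the edgeR refit and the highest of the other splits gave 0, at an adjusted p and also at an unadjusted p of 0.05. With 1 of 10 splits as the smallest possible share, the splits are too few for a share under 0.05, and the genes had been selected on the real split.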
